A study of Caenorhabditis elegans with 12 samples.

How the data were processed

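RNA was measured in whole Caenorhabditis elegans nematodes collected at the fourth larval stage, per the labels' protocols. Animals were grown from hypochlorite-purified eggs, RNA was extracted from frozen pellets with TRIzol, and poly-A enriched libraries were made by a sequencing company. There were 12 libraries in 3 groups of 4: the non-transgenic N2 strain (wild type), a strain with a TDP-43 transgene under the pan-neuronal snb-1 promoter and a dsRED marker under the pharyngeal myo-2 promoter (TDP-43), and a strain with a TDP-43 transgene altered in its nuclear localization signal under the same promoter and a dsRED marker under the body wall muscle myo-3 promoter (TDP-43dNLS). The labels do not say whether the 4 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries.

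The authors deposited 1 table of raw read counts per gene, with 46926 genes and 12 columns, each matched to its sample by name. The submitters' processing notes name STAR, featureCounts 2.20.0, R 4.4.2 and the WBcel235 genome build. The annotation release used, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of overlapping, antisense or near-identical genes could therefore have been counted in either partner. Gene symbols, biotypes and coordinates were taken from an Ensembl annotation of the same build, in which every identifier of the table was found. Total counts ranged from 20671982 to 26910097 per library.

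Counts were analysed in R 4.3.3. Genes with low counts were removed with filterByExpr (minimum count 10), which left 16637 genes holding 99.9% of all counts. Libraries were scaled with TMM, and each of 3 comparisons was tested with the quasi-likelihood test of edgeR 4.0.16 (robust fit over all 12 libraries, no covariate) with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are counts scaled by TMM-adjusted library size, and standard errors were derived from the fitted log2 fold change and its F statistic. Gene lists (32 of them) were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, adjusted over 96 tests. The same test with an estimated correlation and the test fry were run beside it. Calls within a list are also given adjusted over the list alone. These tests, the lists and the alternatives below were fixed before the data were examined, except where stated.

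The rule for naming genes was fixed at the same time. It took genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the 2 groups (up to 10 per direction with a gene-class name and the 2 largest whatever their name), likewise for the overlap of both strains, then the genes linked to the constructs, and up to 4 members of each list with the lowest p. Only zig-2 met the first part. The other genes below were named because they passed the threshold in a fit with a further term, a choice made after their values were seen, and list members were ranked in that fit.

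That term was added after seeing the data. The libraries of each group fell apart in their level of a fixed oocyte and eggshell list. A term with 2 levels (the split term) separates the 4 libraries under 6 on the mean log2 CPM scale from the other 8. It was chosen after the counts of several such adjustments had been seen: the oocyte list level as a covariate, the first principal component, 1 to 3 surrogate variables from sva 3.50.0, and leaving out the 4 libraries. The counts under all of them are given in the closing section. The term is defined from expression, so the fit with it is an added description and not the designed test.

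The other alternatives were DESeq2 size factors and upper-quartile scaling, no filter and a stricter filter (10 CPM in 4 libraries), the Wald test of DESeq2 1.42.0, limma voom, only the groups compared, the replicate number as a block, germ line and cuticle genes left out, and each library left out in turn. The fits were tested on simulated counts with 200 changed genes per strain in each of 3 draws, with 16307 genes tested on average. Changed genes were taken from those with a mean of at least 5 CPM. Counts were drawn from a model with the split term and its dispersions, each gene independently of the others. The fit with that term therefore matches the simulation and the designed fit does not, so the recoveries cannot rank the fits on the real data. The false calls do not cover the choice of the term. For TDP-43 against wild type, the designed fit recovered 0% of genes changed 2-fold and 23% of genes changed 4-fold, with 0 false calls. With the split term, recovery was 28.7% and 87.3%, with 17 false calls over the 3 draws. For TDP-43dNLS against wild type, the designed fit recovered 0.7% and 27.7% with 0 false calls, and the fit with the split term 25.7% and 86.3% with 14. Overlap between the strains was compared with 20 draws of unchanged groups from the same model and with the 6 ways of dividing the wild type libraries 2 and 2 between the comparisons. The labels number the libraries of each group 1 to 4 without saying what a number marks. In wild type and TDP-43, deviations of same-numbered libraries from their group means correlated at 0.229, 0.508, 0.502 and 0.825, so the numbers were taken to pair these 2 groups. That pairing comes from the values alone, and replicate 4 is low in oocyte transcripts in both groups. After the split term was taken out the correlations were 0.302, -0.213, -0.107 and -0.47. That fit makes the deviations of the 4 libraries low in oocyte transcripts sum to 0. The value for replicate 4 is thus partly fixed by the fit and cannot speak to pairing. The other 3 values differ in sign and show no pairing beyond the split. No pair of libraries agreed within sampling noise, so each counted as 1 sample.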

Results

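The series measured poly-A RNA in whole worms of 3 strains, described as fourth-stage larvae, with 4 libraries each: wild type, TDP-43 and TDP-43dNLS. TDP-43 is an RNA-binding protein that is mostly nuclear in healthy cells and accumulates in the cytoplasm of neurons in several neurodegenerative diseases. Both transgenes used the promoter of snb-1, the synaptobrevin gene. The series title frames the work as shared and distinct effects of nuclear and cytoplasmic TDP-43. Totals ranged from 20671982 counts (wild type replicate 3) to 26910097 (TDP-43dNLS replicate 2).

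The largest difference between libraries ran within the groups. Transcripts of oocytes, eggshell and yolk were abundant in 8 libraries and scarce in wild type replicate 4, TDP-43 replicate 4 and TDP-43dNLS replicates 3 and 4. The oocyte and eggshell list had mean levels of 2.26, 3.35, 1.81 and 3.78 log2 CPM in these 4 libraries, against 7.97 to 9.24 in the other 8. The yolk protein gene vit-2 stood at 6.82, 35.2, 3.16 and 83.4 CPM there and at 1555 to 3978 CPM elsewhere. The adult collagen gene col-19 was at 1569 to 3314 CPM in the 8 libraries and at 1.24 to 481 CPM in the 4, so genes of adults were abundant in 8 of the 12 libraries against the larval stage stated for all. The molting gene mlt-10 was at 65.9 to 180 CPM in the 4 libraries and at 7.95 to 63.1 CPM in the other 8. The first principal component of log2 CPM held 69.6% of the variance and separated these 4 libraries from the rest. Pairs of libraries on the same side correlated at 0.89 to 0.977 across genes, and pairs on opposite sides at 0.686 to 0.876. The groups held 1, 1 and 2 such libraries. The common dispersion was 0.435 in the designed fit and 0.137 in the fit with the split term.

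**Figure D1:**
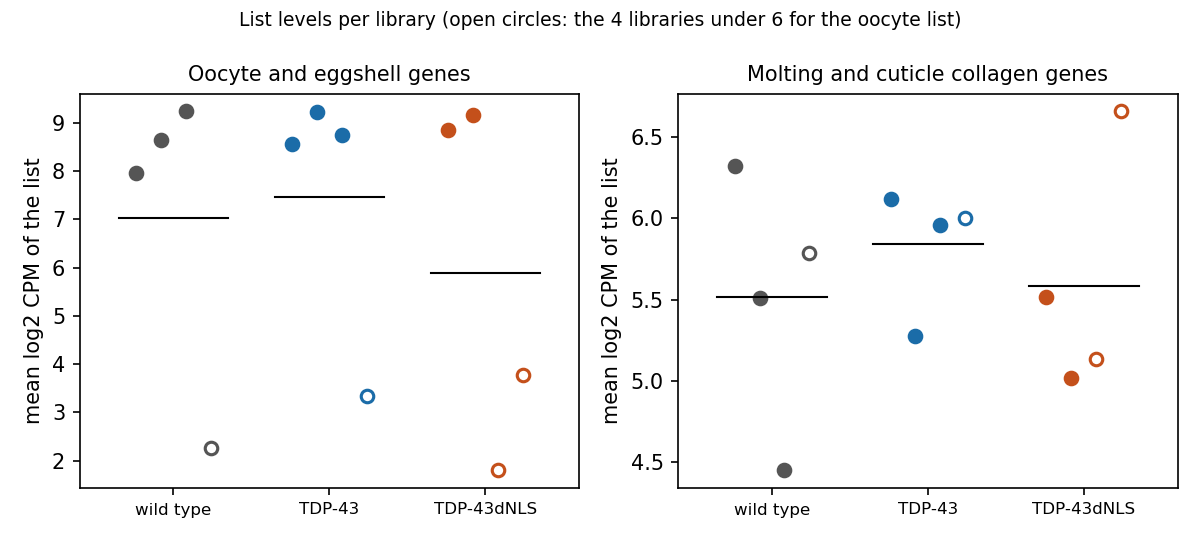
Mean log2 CPM of the oocyte and eggshell list (left) and of the molting and cuticle collagen list (right) in each library, by group, with lines at group means. Open circles mark the 4 libraries below 6 on the oocyte list, which lie between 1.81 and 3.78 while the other 8 lie between 7.97 and 9.24.

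Reads over 2 short annotated stretches, beside the snb-1 and myo-2 promoters named in the genotypes, followed the labels. T10H9.10 (WBGene00198169, chromosome V, 6659021 to 6659161, WBcel235), an annotated non-coding RNA upstream of snb-1, had 0 counts in all 4 wild type libraries. It had 31 to 74 counts in the TDP-43 libraries and 28 to 177 in the TDP-43dNLS libraries. T18D3.14, a stretch upstream of myo-2, had 3, 9, 16 and 10 counts in the TDP-43 libraries and 0 in all others. No stretch beside myo-3, whose promoter is named for TDP-43dNLS, did so: K12F2.3, K12F2.4 and K12F2.5 had 0 counts in all libraries, and T04H1.1 had 103, 121 and 146 over the wild type, TDP-43 and TDP-43dNLS libraries. Transgene sequences were not analysed here, and reads of T10H9.10 cannot be told from reads of the constructs. Endogenous tdp-1, the worm ortholog of TDP-43, was at 89.3 ± 44.4 CPM in wild type, 106 ± 42.3 in TDP-43 and 90.7 ± 56.3 in TDP-43dNLS (SD, n = 4), and did not pass the test in any comparison. Endogenous snb-1 was at 148 ± 14.9, 134 ± 12.4 and 145 ± 34.8 CPM, myo-3 at 485.5 ± 224, 584 ± 314 and 485.8 ± 233, and let-858, a common source of construct terminators, at 96.1 ± 22.4, 114 ± 33.9 and 99.8 ± 29, and none of them passed.

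TDP-43 against wild type set the strain with the unaltered protein against N2, so marker and strain background differ along with the transgene. One gene passed the designed test: zig-2 (WBGene00006979, chromosome X, 12340377 to 12341438), which encodes a secreted immunoglobulin-domain protein. It fell from 20.4 ± 4.43 CPM in wild type to 1.23 ± 0.27 CPM in TDP-43 (SD, n = 4), lower in every TDP-43 library than in any wild type library. Its log2 fold change was -4.05 ± 0.48 (SE), with an adjusted p of 0.0481 in edgeR's quasi-likelihood test. The call was lost when any 1 of 10 of the 12 libraries was left out, and held without TDP-43dNLS replicate 3 or 4, with adjusted p between 7.99e-14 and 0.472 over 29 alternatives. Adding the replicate number as a block to the fit of all 12 libraries gave -4.02 ± 0.50 and an adjusted p of 0.288, with 0 genes past. In a blocked fit of wild type and TDP-43 alone, chosen after that result was seen, it had -4.05 ± 0.34 and an adjusted p of 0.000116 among 22 genes past. That block also takes up the split, because replicate 4 is low in oocyte transcripts in both groups. In the designed fit 304 genes had an unadjusted p under 0.05, and DESeq2 called 19.

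After the split term was added, having seen the data, 16 genes passed: 8 higher and 8 lower in TDP-43. Lower genes included several that neurons use for signalling. CPM of nlp-49 (WBGene00019160, chromosome X), a neuropeptide gene, was 121 ± 48.7 in wild type and 41.1 ± 27.4 in TDP-43, and that of flp-1 (WBGene00001444, chromosome IV), another, 110 ± 41.5 and 34.2 ± 29.1 (SD, n = 4). Both nlp-49 (log2 fold change -1.67 ± 0.21, edgeR adjusted p 0.01) and flp-1 (-1.89 ± 0.25, 0.011) fell, as did unc-25 (WBGene00006762, chromosome III; -1.37 ± 0.18, 0.011), which encodes the glutamate decarboxylase that makes GABA. The transthyretin-related gene ttr-39 fell by 2.01 on the log2 scale (adjusted p 0.00687), and pghm-1, a peptide-amidating enzyme gene, fell by 0.9 (0.0481). zig-2 (adjusted p 0.00566), C53B7.3 and Y75B8A.44 (both 0.0481) were the remaining lower genes. The 8 higher genes were 4 neighbouring pseudogenes on chromosome V between 16924985 and 16933555 (Y102A5C.5, Y102A5C.6, Y102A5C.7 and Y102A5C.35), T10H9.10, C38D9.2, C30G12.1 and mtch-1, a mitochondrial carrier gene. Y102A5C.6 stood at 8.2 ± 4.79 CPM in wild type and 85.6 ± 39.9 in TDP-43, and Y102A5C.5 at 2 ± 1.03 and 28 ± 15.4. How reads shared between such copies were counted is not given, so their separate values are uncertain. Of the 16, zig-2, ttr-39, T10H9.10, Y102A5C.5 and Y102A5C.6 passed under every alternative that gave them a value, while C53B7.3 and pghm-1 did not pass when any 1 library was left out. Of the 12 fits without 1 library, mtch-1 and Y75B8A.44 did not pass in 11, C30G12.1 and Y102A5C.7 in 9, unc-25 in 5, flp-1 in 4, nlp-49 and C38D9.2 in 2, and Y102A5C.35 in 1. The count was 5 without wild type replicate 2, 10 without wild type replicate 4, and 8, 7 and 9 without TDP-43 replicates 1, 2 and 3. In data simulated from a model with the same term this fit made 17 false calls over 3 draws, which does not cover the choice of the term.

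**Figure D2:**
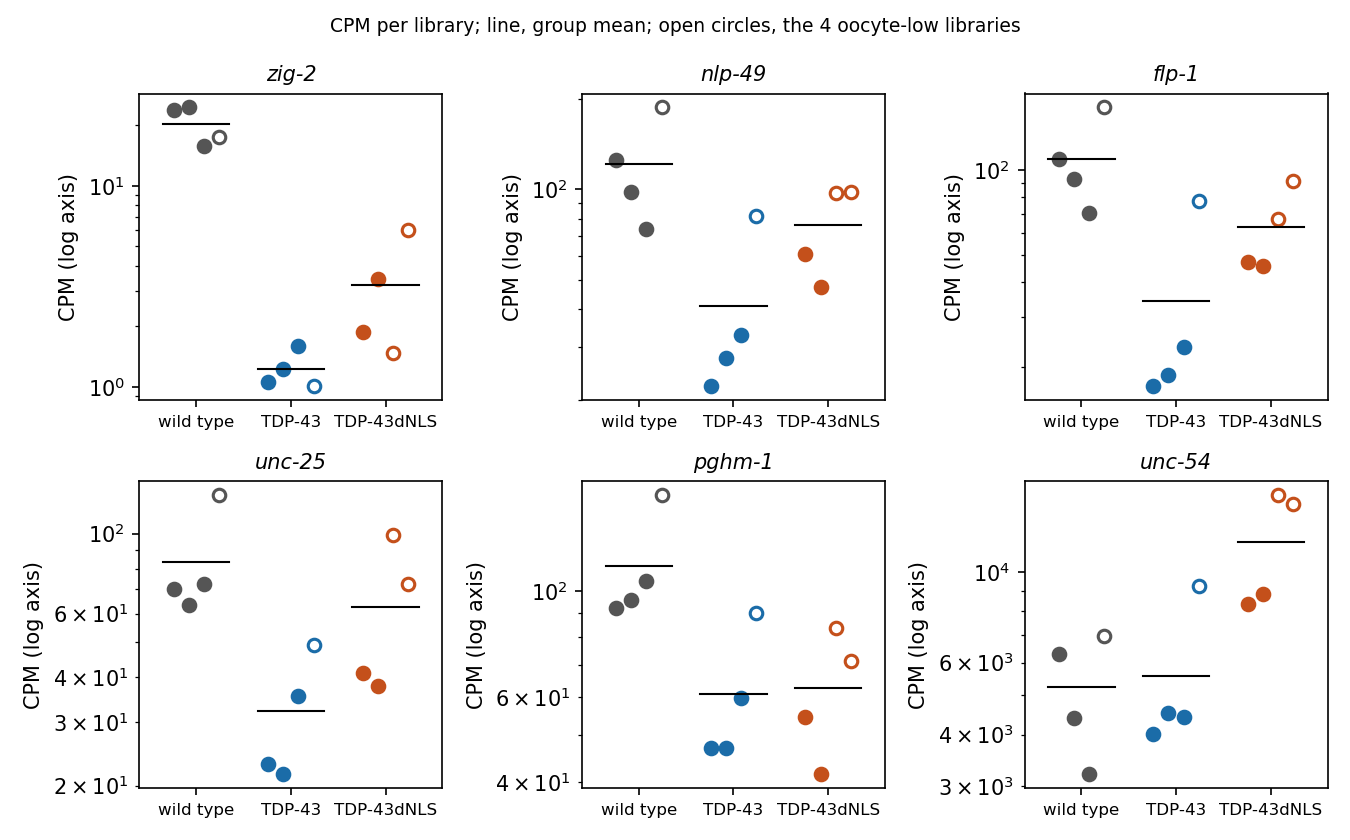
CPM per library on a log axis for zig-2, nlp-49, flp-1, unc-25, pghm-1 and unc-54, by group, with lines at group means and open circles for the 4 libraries low in oocyte transcripts. For zig-2, wild type averages 20.4 CPM, TDP-43 1.23 and TDP-43dNLS 3.2.

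The neuropeptide, neurotransmitter and synaptic release lists lay lower in TDP-43, while the list of touch receptor neuron genes did not: 12 of its 14 members were positive with the split term (median 0.09, adjusted p 0.242, not past). Levels of the 3 lower lists overlapped between the groups. Neuropeptide levels were 3.37, 3.3, 3.67 and 4.34 log2 CPM in TDP-43 replicates 1 to 4 and 4.05, 3.93, 3.85 and 4.34 in wild type. The 2 groups were thus alike in replicate 4. Neurotransmitter levels ran from 2.58 to 3.71 in TDP-43 and from 3.0 to 3.88 in wild type. Synaptic release levels ran from 5.27 to 6.26 and from 5.45 to 6.4. With the split term, 78 of 88 neuropeptide genes had negative log2 fold changes (median -0.34). Of these, 2 passed over all genes and 3 (nlp-49, flp-1 and flp-33) adjusted over the list alone. The list had an adjusted p of 1.02e-13 in camera, and adjusted p = 0.528 with an estimated correlation. In the designed fit 75 of 88 were negative (median -0.3, adjusted p 3.91e-15, and adjusted p = 0.61 with an estimated correlation). Of the 39 neurotransmitter genes, 34 were negative (median -0.32, adjusted p 3.77e-07, and adjusted p = 0.528 with an estimated correlation). The 3 past the threshold adjusted over the list alone were unc-25, the vesicular transporter unc-47 (-1.27 ± 0.3) and its partner unc-46 (-1.17 ± 0.31); 1 of them passed over all genes. Synaptic release genes were negative for 29 of 35 members (median -0.24, adjusted p 1.44e-05, and adjusted p = 0.653 with an estimated correlation), and 0 members passed.

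Outside neurons, the pharynx list had the lowest median in TDP-43 in the fit with the split term. There, 12 of 14 members were negative (median -0.73, adjusted p 6.9e-09, and adjusted p = 0.528 with an estimated correlation), 0 passed over all genes, and 9 fell adjusted over the list alone. They included the pharyngeal myosins myo-1 (-1.07 ± 0.29) and myo-2 (-1.05 ± 0.32) and the troponin genes tni-4 (-0.78 ± 0.24) and tnc-2 (-0.91 ± 0.29). As designed the median was -0.68, and 0 passed over the list alone. Cytochrome P450 and UDP-glucuronosyltransferase genes were negative for 105 of 128 members (median -0.37, adjusted p 4.88e-12, and adjusted p = 0.409 with an estimated correlation). Of them, cyp-34A9 (-1.14 ± 0.24) and cyp-37B1 (-1.86 ± 0.42) fell adjusted over the list alone and 0 over all genes. All 79 ribosomal protein genes were positive (median 0.21, adjusted p 7.46e-17, and adjusted p = 0.653 with an estimated correlation), as were all 31 germ line genes (median 0.37, adjusted p 3.22e-09, and adjusted p = 0.7 with an estimated correlation); no member passed singly. The sperm list (49 of 51 positive, median 0.67, adjusted p 1.15e-06, and adjusted p = 0.725 with an estimated correlation) and the oocyte and eggshell list (24 of 24, 0.38, 0.000582, and adjusted p = 0.736 with an estimated correlation) were higher too, and the intestine list was lower (14 of 15 negative, median -0.28, adjusted p 0.00617, and adjusted p = 0.725 with an estimated correlation). These lists moved together with the neuronal and pharynx lists, and a difference in the share of tissues between the groups was not separated from change within them.

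TDP-43dNLS against wild type set the strain with the altered protein against N2 in the same way. The designed edgeR test called 0 genes, with 241 at an unadjusted p under 0.05, and DESeq2 called 11. Adding the split term gave 9 genes. Higher were Y102A5C.5, Y102A5C.6, Y102A5C.35, C38D9.2 and T10H9.10. Lower were pghm-1 (log2 fold change -1.03 ± 0.15, adjusted p 0.0243), Y19D10B.6 (-1.84 ± 0.23, 0.0149), and the neighbours exh-1 (-2.12 ± 0.32, 0.0385) and C36C5.12 (-2.31 ± 0.32, 0.0229) on chromosome V, 3157086 to 3159352. zig-2 had a log2 fold change of -2.68 ± 0.43 and an adjusted p of 0.0694. Of the 12 fits without 1 library, exh-1 did not pass in 10, Y102A5C.35 in 9, pghm-1 in 8, C36C5.12 in 5, C38D9.2, Y102A5C.6, T10H9.10 and Y19D10B.6 in 3, and Y102A5C.5 in 1. The count was 0 without wild type replicate 2, 5 without wild type replicate 3, 2 without wild type replicate 4, 5 and 17 without TDP-43 replicates 2 and 4, and 1 without TDP-43dNLS replicate 1. It was 0 when only the 2 groups compared were fitted.

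Body wall muscle genes lay lower in TDP-43dNLS, with 1 exception. In the fit with the split term 15 of 16 members were negative (median -0.61), and 11 fell and 1 rose adjusted over the list alone, with 0 past over all genes. The troponin T gene tnt-2 (-0.84 ± 0.19), dim-1 (-0.79 ± 0.18) and the paramyosin gene unc-15 (-0.72 ± 0.18) were among those that fell. The exception was unc-54, the major body wall myosin heavy chain, at 0.93 ± 0.18: its CPM was 5218 ± 1728 in wild type and 11790 ± 3723 in TDP-43dNLS (SD, n = 4). The list had an adjusted p of 1.14e-13 in camera, adjusted p = 0.409 with an estimated correlation, 0.229 in fry's directional test and 0.00539 in its test for change in either direction, which also counts unc-54. As designed the median was -0.52, with 2 down and 1 up adjusted over the list alone, and fry gave 0.966 and 0.861. The pharynx list was also low in TDP-43dNLS with the split term (10 of 14 negative, median -0.34, adjusted p 0.000999, and adjusted p = 0.717 with an estimated correlation), with no member past over the list alone, and did not pass as designed (median 0.07, adjusted p 0.807).

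**Figure D3:**
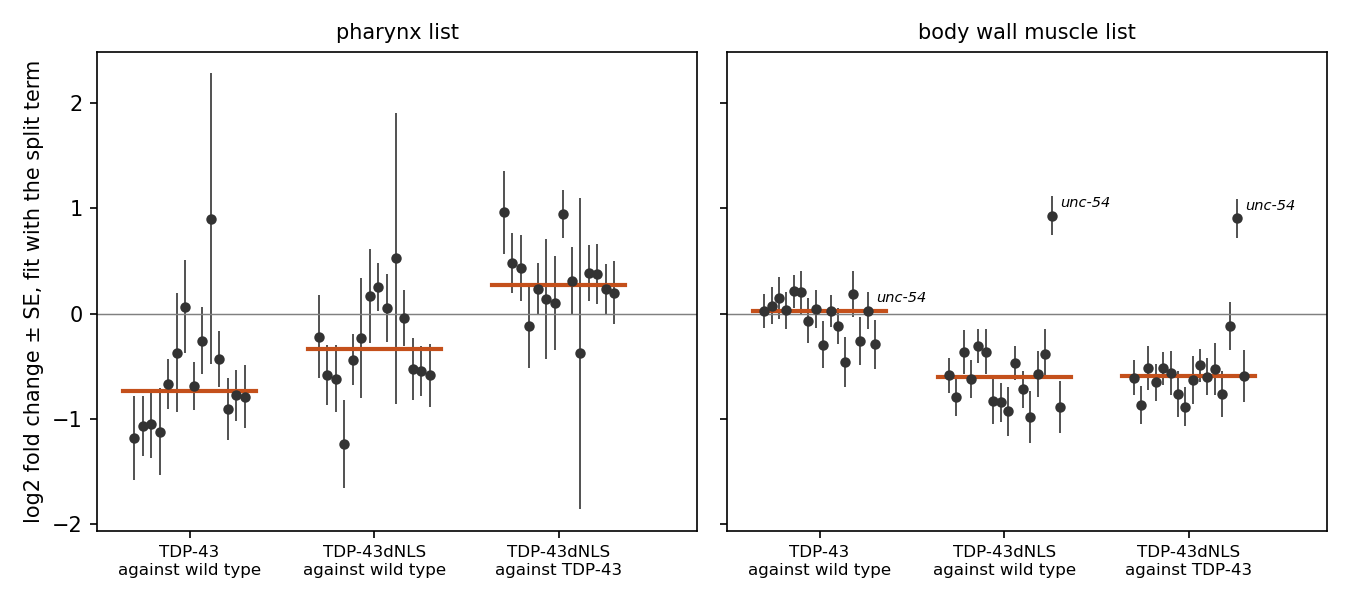
Log2 fold change with standard error of each tested member of the pharynx list (left) and the body wall muscle list (right) in the 3 comparisons, in the fit with the split term, with list medians as bars. The pharynx median is -0.73 in TDP-43 against wild type, and the body wall muscle median is -0.61 in TDP-43dNLS against wild type, where unc-54 lies at 0.93.

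The neuropeptide and neurotransmitter lists were also negative in TDP-43dNLS with the split term: 73 of 88 neuropeptide genes (median -0.22, adjusted p 9.98e-07, and adjusted p = 0.717 with an estimated correlation) and 32 of 39 neurotransmitter genes (median -0.31, adjusted p 2.34e-05, and adjusted p = 0.547 with an estimated correlation). Synaptic release genes were negative for 29 of 35 (median -0.19, adjusted p 0.00016, and adjusted p = 0.717 with an estimated correlation), and ribosomal protein genes positive for 76 of 79 (median 0.16, adjusted p 2.27e-09, and adjusted p = 0.717 with an estimated correlation). nlp-49 (-0.94 ± 0.21) and flp-1 (-1.09 ± 0.25) fell adjusted over the list alone and not over all genes. As designed the neuropeptide and neurotransmitter lists did not pass (camera adjusted p 0.127 and 0.85), and the neurotransmitter median was 0.03. The synaptic release list leaned slightly higher as designed, so its lower value rests on the split term. Its library levels overlapped, at 5.3 to 6.5 log2 CPM in TDP-43dNLS and 5.4 to 6.4 in wild type. Genes of the intracellular pathogen response were positive for 27 of 29 members (median 0.44, adjusted p 0.000688, and adjusted p = 0.653 with an estimated correlation), none past singly. Nuclear-encoded respiratory chain genes were negative for 30 of 32 (median -0.14, adjusted p 4.14e-06, and adjusted p = 0.717 with an estimated correlation), none past singly. The oocyte and eggshell list turned with the fit, from a median of -0.26 as designed to 0.47 with the split term. The germ line list turned as well: all 31 genes were positive with the split term, and the list leaned lower as designed. Its levels ran from 3.4 to 7.08 log2 CPM in TDP-43dNLS and from 3.94 to 6.97 in wild type. A difference in the share of tissues was not separated in this strain either.

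TDP-43dNLS against TDP-43 tested the difference between the strains directly. The designed edgeR test called 0 genes, with 427 at an unadjusted p under 0.05, and DESeq2 called 5. Adding the split term gave 1 gene: C30G12.1 (WBGene00016273, chromosome II, 7299342 to 7301633), at 19 ± 7.65 CPM in TDP-43, 3.03 ± 1.75 in TDP-43dNLS and 4.13 ± 2.63 in wild type (SD, n = 4), with a log2 fold change of -3.09 ± 0.38 and an adjusted p of 0.0415. That call was lost without any 1 of 10 libraries and held, of these fits, only without wild type replicate 1 or 3, with adjusted p between 1.21e-13 and 0.237 over 21 alternatives. Without TDP-43dNLS replicate 2 the count was also 1, from another gene. Among lists, body wall muscle had a median of -0.6 (adjusted p 1.87e-14, and adjusted p = 0.409 with an estimated correlation), with 13 down and 1 up adjusted over the list alone. The pharynx list had a median of 0.27 (adjusted p 0.00322, and adjusted p = 0.717 with an estimated correlation) and the intracellular pathogen response 0.7 (adjusted p 4.17e-08, and adjusted p = 0.528 with an estimated correlation). The strains also differ in their dsRED marker.

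Shared change was measured by overlap and by correlation. In the designed fit 0 genes were called in both strains. With the split term 5 genes were higher in both (Y102A5C.5, Y102A5C.6, Y102A5C.35, C38D9.2 and T10H9.10) and 1 was lower in both (pghm-1), where independent lists would share 0.0024 and 0.00192 genes. Of these, T10H9.10 lies beside the promoter that both constructs carry, so it is no sign of a shared response. Y102A5C.5, Y102A5C.6 and Y102A5C.35 are neighbouring pseudogenes whose separate values are uncertain, so they are not independent of each other. The expected 0.0024 and 0.00192 treat genes as independent and leave out the shared wild type. Simulated unchanged groups against the same controls shared at most 0. The simulation drew each gene independently and holds no changes common to many genes of a library beyond the split. It may therefore understate the overlap by chance and the spread of the correlation below. With the wild type libraries divided between the comparisons, 0 to 2 genes were shared. As designed every division called 0 genes in both strains, so the overlap could only be 0. With the split term TDP-43dNLS had calls only where TDP-43 was set against wild type replicates 3 and 4. That division called 2 genes in TDP-43 and 44 in TDP-43dNLS, and gave the overlap of 2. The divisions are therefore a weak check of sharing. The overlap was 0 without wild type replicate 2, 3 and 2 without wild type replicates 3 and 4, and 1 without TDP-43dNLS replicate 1. Across genes, which are not replicates, the log2 fold changes correlated at 0.311 as designed and 0.559 with the split term, against 0.413 and 0.488 in the simulations. The covariance was 0.0811 against a simulated 0.123 as designed, and 0.158 against 0.108 with the split term. With divided controls the correlation ran from -0.34 to 0.197 as designed and from -0.145 to 0.28 with the split term. Leaving out 1 library moved the designed correlation between 0.131 (without TDP-43 replicate 4) and 0.677 (without wild type replicate 4). It was 0.473 without wild type replicate 3, and 0.171, 0.151 and 0.507 without TDP-43dNLS replicates 1, 2 and 3.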

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

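The tests of the 3 patterns weighed here and in the observations, and the term that splits the libraries, were chosen after the results were seen; the counts of other splits of the samples were predicted before they were seen. Of 290 groups of 4 values tested, 37 had 1 library far from the other 3 by Dixon's criterion, where chance gives about 14.5. Of these, 26 were TDP-43 replicate 4 and 8 were wild type replicate 4, both among the 4 libraries low in oocyte transcripts.

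In TDP-43 replicate 4, the list levels that stood apart were ribosomal proteins at 10.5 log2 CPM, body wall muscle at 10.3, oocyte and eggshell at 3.35 and germ line at 4.61. The muscle genes myo-3 (1050 CPM), unc-54 (9260), tnt-2 (2020), dim-1 (2190), unc-15 (3850), unc-22 (977), ttn-1 (407) and lev-11 (4820) stood above the other 3 libraries. So did Y102A5C.7 (9.3 CPM), flp-1 (77.6), exh-1 (66), C36C5.12 (28.6), Y19D10B.6 (32.2), unc-47 (7.61), ace-1 (24.3), unc-49 (106), ceh-22 (7.57), pgp-14 (149), pals-22 (10.1), ucr-2.2 (169), asb-2 (587) and egl-19 (118). In wild type replicate 4, the sperm list was at 1.31 log2 CPM and the yolk list at 1.09, with C38D9.2 at 3.3 CPM, Y102A5C.7 at 0.575, unc-25 at 128, unc-30 at 14.8, pals-22 at 11.7 and ssp-16 at 3.55. TDP-43dNLS replicate 1 stood apart for ribosomal proteins (9.82 log2 CPM) and C36C5.12 (1.53 CPM), and TDP-43dNLS replicate 2 for cyp-35A3 (17.9 CPM).

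The 2 transgenic strains differed by the direct test for C30G12.1 with the split term (log2 fold change -3.09). In the designed fit, 19 lists differed by camera with the preset correlation and 0 with an estimated correlation. TDP-43dNLS holds more libraries low in oocyte transcripts than TDP-43, which this fit does not take into account. With the split term 15 lists differed, and the oocyte and eggshell list and small RNA pathways were not lower in TDP-43dNLS. The values that follow are those of the designed fit. Medians for TDP-43dNLS against TDP-43 were higher for oxidative stress (0.14), insulin pathway targets (0.57), antimicrobial effectors (0.27), the intracellular pathogen response (1.11), xenobiotic detoxification (0.42), autophagy and lysosome (0.19), synaptic release (0.32), neurotransmitter genes (0.32), neuropeptides (0.26), insulin-like peptides (0.39), pharynx (0.51) and intestine (0.42). They were lower for the proteasome (-0.19), small RNA pathways (-0.18), the respiratory chain (-0.15), body wall muscle (-0.35), sperm (-0.74), oocyte and eggshell (-0.44) and germ line (-0.50).

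The first pattern weighed is the set of 4 libraries low in oocyte and yolk transcripts. A mislabelled sample is argued against, since 0 of the 4 libraries had T10H9.10 or T18D3.14 reads that went against their label, and so is library depth, since 0 of the 4 had a total outside the range of the other 8. An earlier developmental stage of the animals could account for the pattern. The list test did not decide it: only 1 of the 4 had a molting and cuticle collagen level above the highest of the other 8. The bound written for that test, at most 2 of 4, was met, but it was a poor bound, because the list pools collagens made at different times of the molting cycle. Single genes seen before the test go with this explanation: mlt-10 was higher in each of the 4 libraries than in any of the other 8, and the adult collagen gene col-19 was at 1.24 to 481 CPM in the 4 and at 1569 to 3314 CPM in the 8. List members noah-1 (318 to 534 CPM against 8.74 to 88.7) and dpy-2 (108 to 194 against 1.41 to 40) also parted the 4 from the 8. So did the fixed developmental timing list, at 5.98 to 6.27 log2 CPM against 4.45 to 5.3. The labels state the fourth larval stage for all libraries, so why they differ stays open.

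Each count of called genes was set against the 35 ways of dividing its 8 libraries 4 and 4. For TDP-43 against wild type, 1 split, the real one, gave as many genes in each fit (1 gene as designed and 16 with the split term, highest other 0). The real division puts 1 library low in oocyte transcripts on each side, while some of the 35 put both on 1 side. The 35 are therefore not alike, and as designed a chance division is not excluded. The split term was chosen after counts under the real labels had been seen and was held fixed in every split, so for that fit chance is not excluded. Of the 16, T10H9.10 may also follow the labels through reads of the constructs. As designed, where the numbers pair these libraries, only 8 splits part all 4 pairs (real 1, highest other 0), too few for a share under 0.05, so that 1 gene rests on the free splits alone. With the split term, and with the same limit, only the real free split gave as many genes for TDP-43dNLS against wild type (1 split, 9 genes, highest other 0) and for TDP-43dNLS against TDP-43 (1 split, 1 gene, highest other 0). In the designed fit those comparisons called 0 genes, which every one of the 35 splits matches, so their counts say nothing about chance. For TDP-43dNLS against wild type the highest other split called 6953 genes and put the 3 libraries low in oocyte transcripts on 1 side, which points to a structure of the samples. For TDP-43dNLS against TDP-43, also with 3 such libraries, the highest other was 0.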

How the results depend on the processing

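The fits with a library covariate, with the split term, without the 4 libraries low in oocyte transcripts or with a block in 2 groups alone were chosen after the results were seen; the other alternatives were not. Counts below are in the order TDP-43 against wild type, TDP-43dNLS against wild type, TDP-43dNLS against TDP-43 and both strains.

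As designed the counts were 1, 0, 0 and 0, with a correlation of 0.311 between the strains. They were 16, 9, 1 and 6 (correlation 0.559) with the split term, 18, 10, 2 and 7 (0.521) with the oocyte list level, 21, 11, 5 and 7 (0.511) with the first principal component, and 22, 13, 6 and 7 (0.512) with 1 surrogate variable. With 2 surrogate variables they were 45, 20, 6 and 8 (0.571), with 3 they were 109, 54, 10 and 18 (0.512), and without the 4 libraries 9, 6, 0 and 4 (0.539). DESeq2 gave 19, 11, 5 and 5. The first count fell to 0 with upper-quartile scaling, with the stricter filter and with the replicate number as a block, and was 22 (12 up, 10 down) with the block in wild type and TDP-43 alone. The correlation was 0.0979 with the stricter filter and 0.16 with limma voom. Leaving out 1 library gave 0 to 1, 0, 0 and 0 genes, and correlations from 0.131 to 0.677. The common dispersion was 0.435 as designed and 0.137 with the split term; for the other settings the cause was not tested.

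With the split term, no filter gave 25, 18 and 6 genes, and the stricter filter 10 in the first comparison, 0 in the third and 3 in both strains. DESeq2 gave 346, 224, 276 and 108, of which 242, 137 and 215 were not tested in edgeR, with median levels of 0.0279, 0.0454 and 0.0295 CPM. Limma voom gave 4 in the third comparison, and fits of only the groups compared gave 9, 0, 0 and 0. Leaving out 1 library gave 5 to 13, 0 to 17, 0 to 1 and 0 to 6 genes, and correlations from 0.45 to 0.656. Gene by gene, 3698 values of the named genes stayed on their side of the threshold, 181 fell short of it, 45 newly passed and 0 turned. As designed these were 5074, 13, 223 and 0.

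Of 96 list tests, 46 passed as designed and 52 with the split term, and 0 in either with an estimated correlation. Leaving out 1 library gave 37 to 53 and 43 to 59. Adding the split term kept 36 of the 46 and lost 8, and 2 passed in the opposite direction. Replicate numbers did not pair TDP-43dNLS with the other groups: its deviations correlated at 0.304, 0.663, -0.629 and 0.715 with wild type and 0.348, 0.754, -0.562 and 0.676 with TDP-43 in replicates 1 to 4. These values follow which libraries are low in oocyte transcripts. With the split taken out they were 0.205, -0.113, -0.0291 and -0.14 with wild type, and -0.232, 0.154, 0.144 and 0.0154 with TDP-43. The values for replicate 4 are partly fixed by that fit, whose deviations sum to 0 over the libraries low in oocyte transcripts. In the other replicates the numbers set TDP-43dNLS no further apart than the other groups beyond the split. With the block in the fit of all 12 libraries all 46 lists passed and 55 in total; beyond zig-2 it changed no other call of the designed fit given for TDP-43 against wild type. With the split term the block gave 19 (11 of them among the 16), 6, 1 and 5 genes. Depth, 20671982 to 26910097 counts per library, limits what can be said of genes below the filter.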

Other observations

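The tests of the muscle lists and of neighbouring genes in this part, and the split term, were chosen after the results were seen.

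Lists of nuclear RNA biology, fixed before the data were examined, lay slightly higher in both transgenic strains with the split term, as did the germ line list (medians 0.37 and 0.16) and the oocyte and eggshell list (0.38 and 0.47). Splicing factors and nuclear RNA-binding proteins had a median log2 fold change of 0.13 in TDP-43 (35 of 44 positive, camera adjusted p 0.003, and adjusted p = 0.733 with an estimated correlation) and 0.13 in TDP-43dNLS (36 of 44, 0.00822, and adjusted p = 0.736 with an estimated correlation). Nuclear import and export genes had medians of 0.13 (38 of 40, 0.000335, and adjusted p = 0.736 with an estimated correlation) and 0.19 (40 of 40, 1.09e-06, and adjusted p = 0.717 with an estimated correlation). Genes of small RNA pathways had medians of 0.12 (37 of 43, 0.000539, and adjusted p = 0.717 with an estimated correlation) and 0.15 (37 of 43, 0.000591, and adjusted p = 0.717 with an estimated correlation). As designed, the TDP-43dNLS medians of the 3 lists were 0.02, -0.02 and -0.03, and none passed. In wild type replicates 1, 2 and 3 the lists rose by more than their medians with the split term. Splicing stood at 6.46, 6.74 and 7.01 log2 CPM, import and export at 6.39, 6.75 and 7.08, and small RNA at 5.47, 5.74 and 5.88. The germ line list rose with them (6.1, 6.6 and 7.0). The split term does not take up that gradient, so an uneven mix along it is not excluded. The germ line and the oocyte and eggshell lists leaned lower in TDP-43dNLS as designed. Glial genes had a median of -0.52 in TDP-43dNLS (9 of 10 negative, 0.00617, and adjusted p = 0.547 with an estimated correlation), with vab-3 down adjusted over the list alone; as designed the median was 0.09 (adjusted p 0.807).

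Several stress lists did not pass in the fit with the split term, and oxidative stress and glutathione genes passed in TDP-43dNLS against wild type (16 of 27 positive, median 0.02, adjusted p 0.0395, and adjusted p = 0.653 with an estimated correlation). In TDP-43, proteasome genes lay higher (33 of 33 positive, adjusted p 6.75e-05, and adjusted p = 0.736 with an estimated correlation). Lower there were autophagy and lysosome genes (32 of 39 negative, 0.000149, and adjusted p = 0.528 with an estimated correlation), insulin pathway targets (14 of 19, 0.018, and adjusted p = 0.521 with an estimated correlation) and antimicrobial effectors (145 of 208, 7.12e-06, and adjusted p = 0.528 with an estimated correlation). Proteasome genes were higher in TDP-43dNLS too (32 of 33 positive), and did not pass with an estimated correlation. That direction rests on the split term, since the list leaned slightly lower in TDP-43dNLS as designed. Its levels ran from 6.64 to 8.05 log2 CPM there and from 6.8 to 8.04 in wild type. Camera's adjusted p in TDP-43 and TDP-43dNLS against wild type was 0.319 and 0.638 for cytosolic heat shock genes, 0.624 and 0.0814 for the endoplasmic reticulum unfolded protein response, and 0.363 and 0.596 for the mitochondrial one. It was 0.218 and 0.114 for cell death, engulfment and axon injury genes, and 0.392 and 0.947 for developmental timing genes.

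The pharynx list was low in TDP-43, which has the pharyngeal myo-2 marker, and with the split term also in TDP-43dNLS (median -0.34), which lacks it; the body wall muscle list was low in TDP-43dNLS, which has the myo-3 marker, and in TDP-43 its median was 0.03, or -0.16 (13 of 16 negative) without the 4 libraries low in oocyte transcripts. In the 8 libraries not low in oocyte transcripts the pharynx median was -0.97 in TDP-43 and the body wall muscle median -0.62 in TDP-43dNLS, both against wild type. For the pharynx this could not test an uneven number of low libraries, since TDP-43 and wild type each hold 1. TDP-43dNLS holds more. Its body wall muscle levels were higher in the low replicates 3 and 4 (9.6 and 9.46 log2 CPM) than in replicates 1 and 2 (8.81 and 8.86). An uneven number would thus raise that list, and is argued against as the whole cause for body wall muscle. The 8 still differ among themselves. In wild type replicates 1, 2 and 3 the oocyte list rose (7.97, 8.66 and 9.24 log2 CPM). There the pharynx list fell (5.1, 4.8 and 4.1), as did body wall muscle (9.7, 9.4 and 9.1). An uneven mix along that gradient is therefore not excluded. A candidate explanation is the marker construct each strain carries. The gap of 0.87 between the 2 medians in TDP-43dNLS against TDP-43 restates the pattern and lends it no support, the low pharynx list in TDP-43dNLS is not explained by it, and marker and TDP-43 form differ together, so they cannot be told apart here. unc-54 lay 1.56 above the median of the other body wall muscle genes in TDP-43dNLS. Reads of a construct with unc-54 sequence could give that, and more unc-54 RNA in muscle could too; without reads or construct sequences these cannot be told apart.

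Several called genes lie beside each other. Of the 50 genes with the lowest p in the fit with the split term, 11 lay within 20 kb of another for TDP-43 against wild type and 11 for TDP-43dNLS against wild type. Of 1000 random sets of 50 tested genes 0 had as many for either, but the 50 include the neighbours that prompted the test. Without the called genes and their neighbourhoods the counts were 2 and 4, reached by 48.7% and 11.6% of random sets, so chance positions are not excluded beyond the genes first seen. On chromosome II, between C30G12.1 and mtch-1 (7299342 to 7374166), 10 other tested genes with at least 5 CPM had a median log2 fold change of 0.69 in TDP-43, with 8 of 10 positive. An extra copy of this stretch in the TDP-43 strain may account for that, as a hypothesis, but nhr-21 (-0.81 ± 0.32) and hsp-4 (-0.08 ± 0.25) lie inside it and do not follow. Values were also small for F21D12.3 (0.15 ± 0.28) and insc-1 (0.29 ± 0.22). The ends of the stretch were set by called genes. A linked background difference between the strains was not tested.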
